A study of Homo sapiens with 6 samples.

How the data were processed

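The data were read counts per gene for 6 bulk RNA sequencing libraries of human ILC2s, 3 freshly isolated from blood and 3 cultured with IL-1b and IL-2. Libraries were made from total RNA with a Clontech SMARTer Ultra Low RNA kit and a Low Input Library Prep kit, per the labels. Such kits amplify cDNA primed on poly(A) tails and do not mark the strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. No molecular identifiers are named in the labels, so counting intervals and floors cover counting error only. The authors deposited raw counts, 1 file per library. CASAVA 1.8.2, TopHat2, SAMtools 0.1.19 and HTSeq 0.6.1 are named, without roles, in the submitters' processing notes. The genome build and the annotation release are not given in the sources used here, so no coordinates are printed.

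Each file listed 57820 versioned Ensembl gene identifiers and 5 summary lines of HTSeq. Of those lines, 3 were 0 in every file (low alignment quality, not aligned, not unique), so multimapping and unaligned reads had been removed or not recorded. Reads in no feature and ambiguous reads were kept out of library sizes and tests, and their shares are in the report. Identifiers were matched without their version to a human gene table, and 52338 had a symbol. XIST, TSIX and Y-linked genes (521 identifiers) were removed before any step, which left 57299 identifiers, and named genes held 98.9% of the kept counts. Of the genes in the fixed lists, 10 had identifiers that could not be matched (CCL3, CCL4, CCL5, CCL3L1, CCL4L2, CCL18, TXNIP, ACACA, BOP1 and TRAC) and were not analysed here. All mitochondrially encoded genes were at 0 in every library, which looks like a removal before deposit rather than a measurement, and is not stated in the labels.

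Before averaging, replicates were compared. The chi-square per degree of freedom between libraries of a group lay between 27.4 and 62.8 over genes with at least 20 counts, far above sampling noise, so no library was a copy of another. Counts were tested with edgeR 4.0.16 (TMM normalisation, filterByExpr by group, glmQLFit and glmQLFTest) with the group as the only term. Of the kept genes 17174 passed the filter, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. Levels are TMM CPM, and folds come from the fitted log2 fold changes. A fold against 0 counts is a lower bound against 3 counts over the group, and a gene with 1 to 3 counts in a group has a ratio of group totals with an exact binomial 95% interval. With so few counts, a fitted log2 fold change depends on the prior count. Library shares were compared by 2-sided exact permutation tests.

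In total, 32 gene lists were fixed before the data were examined. They were type 2 cytokines, ILC2 identity genes, type 1 and type 3 programmes, IL-1 family receptors and signalling, NF-kB targets, IL-2 and STAT5 targets, TNF family and co-stimulatory molecules, chemokines, homing and adhesion receptors, lipid mediator genes, resting lymphocyte genes, immediate early genes, cell cycle, glycolysis, cholesterol synthesis, fatty acid synthesis, amino acid transport and serine synthesis, ribosome biogenesis, oxidative phosphorylation, interferon-stimulated, unfolded protein response and heat shock genes, apoptosis regulators, markers of T, B and NK cells, of monocytes and dendritic cells, of basophils, mast cells and eosinophils, of platelets and erythroid cells and of progenitors, mitochondrially encoded genes and ribosomal proteins. The 29 lists with at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), and again with an estimated correlation. In that second setting camera also bases its degrees of freedom on the number of libraries and not of genes. Its p-values are therefore larger even at an equal correlation. Some genes are in several lists. The genes named in the text follow a rule also fixed before the data were examined. It took the 12 largest rises and the 12 largest falls among called genes without overlap between groups and with a mean of at least 10 CPM, excluding clone and pseudogene names, then 30 fixed genes, and up to 4 members of each list with the smallest p. Other genes were named after their values were seen, because they made up a count of 5 or fewer members or stood out in a library. These include IL3, STAT4, RUNX3, IRF1, IRAK2, PELI1, IL4R, CDKN1A, BCL6, MCM7, XBP1, GNLY, CCR3, CSF2RB, IL2, IFI27 and the named members of lists without values.

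Replicate numbers are shared by the groups, and the labels do not say what a number marks. Deviations of same-numbered fresh and cultured libraries from their group means correlated at 0.125, 0.187 and 0.145 over 17174 genes, against -0.133 to -0.00662 for other pairs. The numbers may thus pair the libraries. Deviations within a group sum to 0, which pushes other pairs below 0 where same-numbered ones lie above it. The pairing rests on this check alone, and the main edgeR, camera and permutation tests do not use it. A fit with the replicate number as a block was an alternative, and its value is given beside results whose call it ended. Other alternatives were DESeq2 1.42.0, limma-voom, other size factors, other filters, stricter thresholds (adjusted p under 0.01, or glmTreat against a fold of 1.5), removal of ribosomal protein genes, and leaving out each library. For lists they were fry, ranks, a prior count of 0.5 and an estimated correlation. The estimated correlation together with the block was chosen after seeing the data. On simulated counts with the real means and library sizes (17174 genes, 50 changed at each fold), the edgeR step found 0 of 50 genes at 1.5-fold, 2 at 2-fold, 22 at 4-fold and 36 at 8-fold, and 4 of its 64 calls were false. The share of changed genes was far smaller than the 51.1% called in the real data. The adjusted threshold depends on that share, so these recoveries need not hold for the real data. In simulated lists of 25 genes, camera called 10 of 10 raised 2-fold and 0 of 100 unchanged with either correlation. Genes were simulated independently of each other, so these counts do not show how the preset correlation performs on lists whose members vary together. Analyses used R 4.3.3, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.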

Results

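Gene-level read counts were analysed for 6 RNA sequencing libraries of human group 2 innate lymphoid cells (ILC2s), lymphocytes that lack rearranged antigen receptors and secrete IL-5 and IL-13. In 3 libraries the ILC2s had been freshly isolated from the peripheral blood of healthy donors, and in 3 they had been cultured ex vivo with IL-1b and IL-2, each at 10 ng/ml. The series design calls the 3 libraries of each group biological replicates. The growth protocol of the freshly isolated samples also names IL-2 at 10 ng/ml, although their labels call them freshly isolated, so it is not clear whether they had any contact with medium. There was no group cultured without IL-1b, so IL-1b, time in culture and cell division cannot be separated, and whether exposure to IL-2 differed is not clear from the labels. Reads assigned to genes numbered 20229567, 14348711 and 14240179 in fresh replicates 1 to 3, and 9479313, 20249038 and 5008778 in cultured replicates 1 to 3. Below, "fresh" and "cultured" name the groups, levels are CPM (read counts scaled to library size) with TMM normalisation as mean ± SD (n = 3 per group), and folds come from the edgeR model.

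The comparison asks how the transcriptome of IL-1b-primed ILC2s differs from that of ILC2s taken directly from blood. Cultured ILC2s carried far more transcript of the cytokine genes IL5, IL13 and IL4, of the alarmin receptor genes IL1RL1 and IL17RB and of the proliferation marker gene MKI67. Fresh ILC2s carried more transcript of FOS and FOSB, of the transcription factor genes KLF2 and TCF7 and of the migration receptor genes S1PR1 and CXCR4. Of 17174 genes tested, 4419 were higher and 4359 lower in cultured cells (edgeR quasi-likelihood test, adjusted p under 0.05), which is 51.1% of the tested genes. At least 4-fold changes were found for 2414 of the higher and 1878 of the lower genes. The groups did not overlap in 62.8% of all tested genes, where chance alone gives 10%. Among 11868 protein-coding genes, 3786 were higher and 2785 lower. Correlations of log2 CPM over the tested genes were 0.914 to 0.932 between fresh libraries, 0.958 to 0.972 between cultured libraries and 0.724 to 0.747 across the groups. These correlations are across genes, which are not independent replicates.

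Among the 12 largest rises in genes with a mean of at least 10 CPM, DLGAP5, HJURP and UBE2C, which act in chromosome segregation, rose 493-fold, 436-fold and 373-fold. CCR1, a receptor for inflammatory chemokines, rose from 0.447 ± 0.46 to 291 ± 46 CPM, 582-fold (edgeR adjusted p = 7.08e-05). TNFRSF8, which encodes CD30, rose from 0.443 ± 0.361 to 176 ± 109 CPM, and the granzyme gene GZMA rose from 1.4 ± 0.623 to 558 ± 36.3 CPM, 395-fold and 394-fold. PTGIS, the prostacyclin synthase gene, rose from 0.117 ± 0.203 to 40.8 ± 30.8 CPM. The remaining 5 of the 12 largest rises had 1 to 3 counts in the fresh group. TCN1, which encodes a vitamin B12 binding protein, had 1 fresh and 2398 cultured counts, a ratio of 3359, with a 95% counting interval of 602 to 132735. GCSAML had 1 and 2081 counts, a ratio of 2915, with a 95% counting interval of 523 to 115195. The kinesin gene KIF18B had 1 and 912 counts, a ratio of 1278, with a 95% counting interval of 229 to 50515. CD33, a sialic acid binding receptor of myeloid cells, had 2 and 1142 counts, a ratio of 799.9, with a 95% counting interval of 221 to 6613. PLXNA4, a semaphorin receptor gene, had 3 and 881 counts, a ratio of 411, with a 95% counting interval of 140.3 to 1999. The fitted log2 fold changes of HJURP (8.77), UBE2C (8.54), CCR1 (9.19), TNFRSF8 (8.62), PTGIS (8.47), TCN1 (10.87), GCSAML (10.77), KIF18B (9.84) and PLXNA4 (8.50) moved by over 1.5 times in fold when 1 library was left out, to 7.76 for UBE2C, 10.27 for CCR1, 7.68 for PTGIS, 10.17 for TCN1, 12.30 for GCSAML, 11.38 for KIF18B and 11.25 for PLXNA4 without fresh replicate 1; 10.06 for HJURP, 11.05 for UBE2C, 9.33 for TNFRSF8, 12.12 for PTGIS and 12.56 for TCN1 without fresh replicate 2; 7.69 for PTGIS and 10.20 for TCN1 without cultured replicate 2.

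The largest falls included transcription factors of the early stimulus response. FOSB fell from 545 ± 232 to 0.959 ± 0.279 CPM, 614-fold (edgeR adjusted p = 3.54e-05), and FOS fell from 584 ± 506 to 2.16 ± 0.95 CPM, 277-fold. KLF4 and NR4A2 fell 247-fold and 200.2-fold, and DUSP1, a phosphatase of MAP kinases, fell 130.2-fold. ABCA1, a cholesterol exporter, fell from 976 ± 316 to 6.58 ± 3.56 CPM, 141-fold. SCML1, EFHC2, PMEPA1 and MPP7 fell 289.7-fold, 187-fold, 139-fold and 130.3-fold. The Notch target HES1 had 1546 fresh and 3 cultured counts, a ratio of 368, with a 95% counting interval of 126 to 1786 for fresh over cultured. COL1A1, a collagen gene, had 1032 fresh and 2 cultured counts, a ratio of 368, with a 95% counting interval of 102 to 3046 for fresh over cultured. With 1 library left out, the fitted log2 fold changes of FOS (-8.11), KLF4 (-7.95), NR4A2 (-7.65), DUSP1 (-7.02), SCML1 (-8.18), EFHC2 (-7.55), PMEPA1 (-7.12) and HES1 (-8.26) moved by over 1.5 times in fold, to -7.24 for KLF4 and -6.10 for PMEPA1 without fresh replicate 2; -7.19 for FOS and -6.09 for DUSP1 without fresh replicate 3; -9.33 for KLF4 and -9.24 for HES1 without cultured replicate 1; -7.25 for KLF4, -7.23 for SCML1, -6.70 for EFHC2 and -6.47 for PMEPA1 without cultured replicate 2; -8.85 for NR4A2 and -9.19 for EFHC2 without cultured replicate 3.

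IL13 and IL5 were the most abundant transcripts of the type 2 cytokine list in cultured ILC2s. IL5 (ENSG00000113525.5, chromosome 5) rose from 19 ± 15.6 to 2487 ± 979 CPM, 131-fold and 7.03 ± 0.68 on the log2 scale (± SE, edgeR adjusted p = 0.000156). IL13 (ENSG00000169194.5, chromosome 5) rose from 65.1 ± 43.5 to 3599.9 ± 1372 CPM, 55.3-fold and 5.79 ± 0.56 (edgeR adjusted p = 0.000153). IL4 (ENSG00000113520.6, chromosome 5) rose from 0.692 ± 0.612 to 49.4 ± 20.7 CPM, 67.9-fold, and CSF2 (ENSG00000164400.4, chromosome 5), which encodes GM-CSF, rose from 99 ± 91.3 to 1192 ± 513 CPM, 12-fold. LIF, an IL-6 family cytokine gene, rose from 7.3 ± 2.96 to 806 ± 85.4 CPM, 110.4-fold. IL9, a mast cell growth factor gene, stood at 3.17 ± 4.99 CPM in fresh and 3.74 ± 1.1 in cultured cells, which did not pass (edgeR adjusted p = 0.881). Without fresh replicate 2, which held the highest IL9 level, the log2 fold change was 3.66 (adjusted p = 0.00506, and 0.00506 to 0.985 over all alternatives), and it was -0.42 and -0.36 without fresh replicates 1 and 3. AREG, the amphiregulin gene, had 3 fresh and 0 cultured counts and was not tested, and reads that fit a near-identical copy of it may be missing from its count. In the list of type 2 cytokines 6 rose and 1 fell of 9 tested, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0168, and adjusted p = 0.392 with an estimated correlation). The member that fell was IL3, on chromosome 5, from 8.48 ± 2.12 to 1.57 ± 1.48 CPM (edgeR adjusted p = 0.0188). The fall of IL3 was not past the threshold without cultured replicate 2 (adjusted p = 0.0839). The fitted log2 fold changes of IL5 (7.03), IL13 (5.79), IL4 (6.09), CSF2 (3.59) and IL3 (-2.53) moved by over 1.5 times in fold when 1 library was left out, to 7.90 for IL5, 6.45 for IL13 and 4.65 for CSF2 without fresh replicate 2; 5.48 for IL4 without fresh replicate 3; -3.36 for IL3 without cultured replicate 3.

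**Figure D1:**
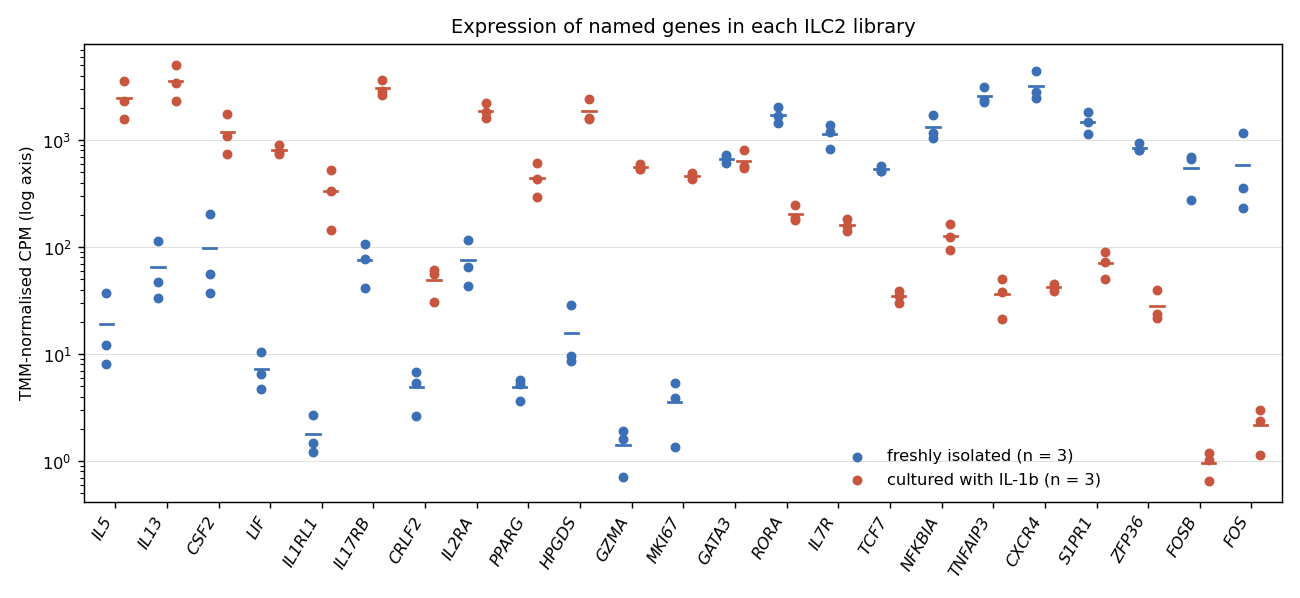
TMM-normalised CPM (log axis) of named genes in each library; points are libraries, 3 freshly isolated (blue) and 3 cultured with IL-1b (red), and short lines are group means. IL5 stood at 3529, 1588 and 2343 CPM in the cultured libraries and at most 36.9 in the fresh ones, while the groups overlap at GATA3.

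The genes that define ILC2s moved in both directions. GATA3, the transcription factor that specifies ILC2s, was expressed at 672 ± 61.6 CPM in fresh and 643 ± 145 in cultured cells and did not differ past the threshold (log2 fold change -0.06 ± 0.20, edgeR adjusted p = 0.806). The sign of that difference depended on the libraries, with 0.049 and 0.077 without cultured replicates 2 and 3. RORA, a nuclear receptor needed for ILC2 development, fell from 1721 ± 297 to 205 ± 36.7 CPM, 8.4-fold (edgeR adjusted p = 6.88e-05), and IL7R, the IL-7 receptor gene, fell from 1137 ± 280.4 to 159.9 ± 22.1 CPM, 7.12-fold. TCF7, which encodes TCF-1, fell from 532 ± 29.8 to 34.6 ± 4.6 CPM, 15.4-fold. Genes for a chain of the receptors for the alarmins IL-33, IL-25 and TSLP rose, although IL7R, which also encodes a chain of the TSLP receptor, fell. IL1RL1, which encodes ST2, rose from 1.78 ± 0.783 to 334 ± 192 CPM, 189-fold, IL17RB rose from 75 ± 32.8 to 3044 ± 507 CPM, 40.6-fold, and CRLF2 rose from 4.92 ± 2.13 to 49.4 ± 16.3 CPM, 10.1-fold. PPARG, a nuclear receptor, rose from 4.88 ± 1.08 to 445 ± 158 CPM, 91.6-fold. PTGDR2, which encodes the prostaglandin D2 receptor CRTH2, rose from 54.5 ± 5.71 to 126 ± 40.8 CPM, 2.32-fold. KLRG1, an inhibitory lectin receptor gene, rose from 72.4 ± 13.5 to 212 ± 136 CPM (edgeR adjusted p = 0.0286), but not past the threshold with upper-quartile factors (adjusted p = 0.0501, and 0.00123 to 0.116 over all alternatives) or without fresh replicates 1, 2 or 3 or cultured replicates 1 or 2 (adjusted p from 0.0547 to 0.116). In the list of ILC2 identity genes 13 rose and 7 fell of 26 tested, or 13 and 7 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.177).

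Several genes of the type 1 programme, that of interferon-gamma secreting lymphocytes, rose in culture. The perforin gene PRF1 rose from 8.56 ± 3.11 to 255 ± 87.2 CPM, 29.6-fold (edgeR adjusted p = 9.15e-05), and NKG7 rose 15.1-fold. TBX21, which encodes T-bet, rose from 2.22 ± 1.35 to 18.2 ± 7.05 CPM, 8.13-fold, and IL18R1 rose 3.09-fold. PRF1 and NKG7 are also NK cell markers and were highest in cultured replicate 3, at 344 and 319.6 CPM, where the NK cell genes GNLY and FCGR3A stood at 397 and 26.2 CPM. The NK cell list was called higher (camera adjusted p = 0.0354, and adjusted p = 0.451 with an estimated correlation), but not without cultured replicate 3 (adjusted p = 0.115). IFNG stood at 7.07 ± 9.39 CPM in fresh and 19.5 ± 19.3 in cultured cells and did not pass (edgeR adjusted p = 0.329), although it did without fresh replicate 2 (adjusted p = 0.0395, and 0.0395 to 0.863 over all alternatives). IL12RB2 stood at 2.29 ± 0.913 CPM in fresh and 8.11 ± 6.94 in cultured cells (edgeR adjusted p = 0.0828). It passed with DESeq2 (adjusted p = 0.0343), without a count filter (0.0421) and without cultured replicate 2 (0.0193, and 0.0193 to 0.338 over all alternatives). Of the type 1 list, 11 rose and 3 fell of 20 tested, or 11 and 3 adjusted over the list alone (camera adjusted p = 0.00744, and adjusted p = 0.332 with an estimated correlation). The members that fell were the transcription factors STAT4, RUNX3 and IRF1, and STAT4 did not pass without cultured replicates 1 or 3 (adjusted p from 0.0573 to 0.0638).

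The type 3 list, named for IL-17 and IL-22 secreting cells, had only higher members among its calls. IL22 rose from 0.314 ± 0.484 to 30.1 ± 26.8 CPM, 82.6-fold (edgeR adjusted p = 0.00271), with 23.6, 7.24 and 59.5 CPM in the cultured libraries. IL26 rose from 0.485 ± 0.532 to 105 ± 28.7 CPM, 227-fold, the transcription factor gene BATF rose from 6.47 ± 5.41 to 343 ± 14.8 CPM, 52.2-fold, NRP1 rose 105-fold and NCR1, which encodes NKp46, rose from 0.0972 ± 0.0841 to 7.13 ± 2.18 CPM. KIT rose from 92.3 ± 32.1 to 181 ± 74.5 CPM (edgeR adjusted p = 0.0413), but did not pass with upper-quartile factors (adjusted p = 0.116), with the 5 CPM filter (0.0667, and 0.00544 to 0.147 over all alternatives) or without fresh replicates 1 or 2 or cultured replicates 2 or 3 (adjusted p from 0.0578 to 0.147). In all, 10 rose and 0 fell of 17 tested, or 10 and 0 adjusted over the list alone (camera adjusted p = 0.00516, and adjusted p = 0.392 with an estimated correlation). With 1 library left out, the fitted log2 fold changes of IL22 (6.37), IL26 (7.83), BATF (5.70) and NRP1 (6.71) moved by over 1.5 times in fold, to 9.31 for IL22 and 6.55 for BATF without fresh replicate 1; 8.53 for NRP1 without fresh replicate 2; 9.12 for IL26 without fresh replicate 3; 5.49 for IL22 without cultured replicate 3.

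Components of IL-1 receptor signalling rose more often than they fell, while NF-kB target genes fell more often than they rose. IL1RAP, the shared co-receptor of IL-1 and IL-33, rose from 23.2 ± 2.27 to 98.1 ± 5.44 CPM, 4.22-fold (edgeR adjusted p = 0.000152). IL1R1, the receptor for IL-1b itself, stood at 2.59 ± 2.33 CPM in fresh and 3.31 ± 1.92 in cultured cells and did not pass (edgeR adjusted p = 0.809). Its log2 fold change of 0.31 ± 0.99 was -0.28 without fresh replicate 2 and -0.0047 without cultured replicate 1. Of IL-1 family receptors and signalling genes, 9 rose and 3 fell of 19 tested, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.188). The members that fell were TAB2, PELI1 and IRAK2, and IRAK2 did not pass with the replicate block (adjusted p = 0.0535, and 0.0104 to 0.133 over all alternatives) or without fresh replicates 1 or 2 or cultured replicates 1 or 2 (adjusted p from 0.0665 to 0.133). Of NF-kB targets, 5 rose and 14 fell of 31 tested, or 5 and 15 adjusted over the list alone (camera adjusted p = 0.101), and the list passed with the 5 CPM filter (camera adjusted p = 0.0205, and 0.0205 to 0.473 over all alternatives that used camera). The feedback inhibitors NFKBIA and TNFAIP3 fell from 1311 ± 361 to 127 ± 35.4 CPM and from 2578 ± 484 to 36.7 ± 14.7 CPM, 10.3-fold and 70.8-fold, and the subunit genes NFKB1 and REL fell 4.76-fold and 4.34-fold. Those that rose were CXCL8, TRAF1, TRAF2, BIRC3 and TNFAIP2, the last not past the threshold without cultured replicate 2 (adjusted p = 0.0546).

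Of IL-2 and STAT5 target genes, 18 rose and 3 fell of 27 tested, or 19 and 3 adjusted over the list alone (camera adjusted p = 0.000594, and adjusted p = 0.354 with an estimated correlation). CISH, a feedback inhibitor of cytokine receptors, rose from 10.1 ± 7.38 to 422 ± 109 CPM, 41.5-fold (edgeR adjusted p = 0.00021). IL2RA, which encodes CD25, rose from 75 ± 37.3 to 1888 ± 299 CPM, 25.2-fold, and DUSP6 and the survival gene BCL2L1 rose 21.3-fold and 18.2-fold. The members that fell were BCL6, IL4R and CDKN1A. IL4R did not pass without cultured replicate 2 (adjusted p = 0.0514), nor CDKN1A without cultured replicate 2 (adjusted p = 0.0553). The fitted log2 fold change of CISH (5.37) moved by over 1.5 times in fold when 1 library was left out, to 6.06 without fresh replicate 1.

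Co-stimulatory, homing and lipid mediator genes also changed. Of TNF family and co-stimulatory molecules, 17 rose and 5 fell of 27 tested, or 19 and 6 adjusted over the list alone (camera adjusted p = 0.00675, and adjusted p = 0.392 with an estimated correlation). TNFSF10, which encodes the death ligand TRAIL, rose from 106 ± 7.03 to 2328 ± 535 CPM, 22-fold (edgeR adjusted p = 3.13e-05), and CD200R1 rose 6.95-fold. CD28 fell from 98.2 ± 25.3 to 5.19 ± 1.09 CPM, 18.7-fold, and TNFRSF25, TNFRSF1A, TNFRSF10B and CD69 also fell. Leaving out a library ended the calls of TNFRSF25 without fresh replicate 3 or cultured replicates 1, 2 or 3 (adjusted p from 0.0752 to 0.112), of TNFRSF1A without cultured replicates 1, 2 or 3 (adjusted p from 0.0517 to 0.0648), of TNFRSF10B without cultured replicates 1 or 2 (adjusted p from 0.0595 to 0.0655) and of CD69 without fresh replicate 3 or cultured replicates 1 or 2 (adjusted p from 0.104 to 0.123). Of homing and adhesion receptors, 13 rose and 7 fell of 24 tested, or 13 and 8 adjusted over the list alone (camera adjusted p = 0.21). CXCR4, the receptor that retains cells in bone marrow, fell from 3226 ± 1028 to 42.4 ± 3.37 CPM, 76-fold, and S1PR1, the receptor for exit from tissue, fell from 1477 ± 352 to 70.7 ± 19.7 CPM, 20.9-fold. The integrin gene ITGAL rose 8.39-fold. Among lipid mediator genes, 13 rose and 1 fell of 19 tested, or 13 and 1 adjusted over the list alone (camera adjusted p = 0.000673, and adjusted p = 0.213 with an estimated correlation). HPGDS, the prostaglandin D2 synthase gene of blood cells, rose from 15.6 ± 11.2 to 1872 ± 478 CPM, 119.9-fold. HPGD, which breaks prostaglandins down, rose from 78.6 ± 6.16 to 769 ± 203 CPM, 9.79-fold, and ALOX5AP, needed for leukotriene synthesis, rose 17-fold. The member that fell was the prostaglandin E2 receptor gene PTGER4, 7.69-fold. In the chemokine list, 2 rose and 0 fell of 8 tested, or 2 and 0 adjusted over the list alone (camera adjusted p = 0.212), and without fresh replicate 2 the list passed (camera adjusted p = 0.0119, and 0.0119 to 0.628 over all alternatives that used camera). The members that rose were CXCL8, from 51.8 ± 29.9 to 320.4 ± 199 CPM, and CXCL10, from 1.06 ± 0.851 to 61.4 ± 72.2 CPM. With 1 library left out, the fitted log2 fold changes of HPGDS (6.91) and CXCL10 (5.83) moved by over 1.5 times in fold, to 7.63 for HPGDS without fresh replicate 2; 4.27 for CXCL10 without cultured replicate 1.

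Of cell cycle genes, 39 rose and 0 fell of 40 tested, or 39 and 0 adjusted over the list alone (camera adjusted p = 4.27e-15, and adjusted p = 0.123 with an estimated correlation). This was the smallest adjusted p of any list at the preset correlation, while with an estimated correlation and with fry the smallest was that of resting lymphocyte genes. MKI67, the proliferation marker gene, rose from 3.53 ± 2.02 to 459 ± 29.5 CPM, 132-fold (edgeR adjusted p = 6.88e-05). TK1, CDK1, CDC45 and HMMR rose 111-fold, 49.8-fold, 48.6-fold and 72.8-fold. The member that did not pass was MCM7, a helicase subunit gene, at 338 ± 52.1 CPM in fresh and 395 ± 80.6 in cultured cells, with a log2 fold change of 0.23 ± 0.21, or -0.043 with upper-quartile factors.

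Metabolic lists moved less uniformly. Of glycolysis genes, 12 rose and 2 fell of 21 tested, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00988, and adjusted p = 0.392 with an estimated correlation). ENO1 and TPI1 rose from 258 ± 70.6 to 2229 ± 226 CPM and from 134 ± 54.5 to 837 ± 44.5 CPM, 8.65-fold and 6.23-fold, and PFKP rose 3.82-fold. PFKFB3, a regulator of the pathway, and the glucose transporter gene SLC2A3 fell, PFKFB3 5.14-fold. Of amino acid transport and serine synthesis genes, 14 rose and 7 fell of 25 tested, or 15 and 7 adjusted over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.354 with an estimated correlation). With the replicate block this list did not pass (camera adjusted p = 0.0523). It also did not pass with the 5 CPM filter (0.072), with a prior count of 0.5 (0.0526, and 0.0186 to 0.422 over all alternatives that used camera) or without fresh replicate 3 (adjusted p = 0.0539). SHMT2 and MTHFD2, mitochondrial enzymes of the folate cycle, rose 13.1-fold and 10.6-fold, the glutamine transporter gene SLC1A5 rose 12.8-fold, and the stress factor gene DDIT3 fell 5.7-fold. Of oxidative phosphorylation genes, 15 rose and 4 fell of 29 tested, or 15 and 4 adjusted over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.406 with an estimated correlation). That call was also lost with the replicate block (camera adjusted p = 0.0546), with the 5 CPM filter (0.126, and 0.0257 to 0.422 over all alternatives that used camera) and without fresh replicates 2 or 3 (adjusted p from 0.0755 to 0.0916). UQCRC1 and COX5B rose 9.98-fold and 7.02-fold, and NDUFV2, NDUFB9, UQCRB and COX4I1 fell. UQCRB did not pass without cultured replicate 3 (adjusted p = 0.0539).

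Lipid synthesis, ribosome biogenesis, protein folding and apoptosis lists did not pass. Of cholesterol synthesis genes, 8 rose and 5 fell of 23 tested, or 8 and 5 adjusted over the list alone (camera adjusted p = 0.471). PMVK rose 7.47-fold, while IDI1, INSIG1, HMGCS1, SQLE and SREBF2 fell, SQLE not without cultured replicates 1 or 2 (adjusted p from 0.057 to 0.0691). In the fatty acid list, 4 rose and 2 fell of 16 tested, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.418). ELOVL6, ACSL4, ACLY and SCD rose and ACSL1 and ACSL3 fell. SCD did not pass without fresh replicate 3 or cultured replicate 2 (adjusted p from 0.0515 to 0.0653), and ACSL3 did not without cultured replicates 2 or 3 (adjusted p from 0.0577 to 0.0609). Of ribosome biogenesis genes, 7 rose and 4 fell of 24 tested, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.425). RRP9 and WDR12 rose 6.71-fold and 4.1-fold, and POLR1C, FBL, NOP58 and GNL3 fell. GNL3 did not pass with DESeq2 (adjusted p = 0.0916), without a count filter (0.151), with the replicate block (0.064, and 0.00627 to 0.574 over all alternatives) or without fresh replicate 1 or cultured replicates 1, 2 or 3 (adjusted p from 0.0528 to 0.193). In the unfolded protein response and heat shock list, 9 rose and 1 fell of 23 tested, or 9 and 1 adjusted over the list alone (camera adjusted p = 0.0545). The list passed with library size alone (0.0498) and without fresh replicate 1 (0.0448), cultured replicate 2 (0.0422) or cultured replicate 3 (0.0272, and 0.0272 to 0.585 over all alternatives that used camera). PDIA4, CALR and PDIA6, which act in the endoplasmic reticulum, rose 16.5-fold, 7.34-fold and 5.24-fold, and XBP1 fell, but not without cultured replicates 2 or 3 (adjusted p from 0.0678 to 0.0704). Of apoptosis regulators, 10 rose and 5 fell of 22 tested, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.21). BIRC5 rose 59.1-fold, and BIRC2, MCL1, BCL2L11, BIK and CASP8 fell. MCL1 did not pass without cultured replicates 2 or 3 (adjusted p from 0.0688 to 0.0721), nor BIK without cultured replicates 1, 2 or 3 (adjusted p from 0.0513 to 0.0599).

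Of resting lymphocyte genes, 0 rose and 18 fell of 24 tested, or 0 and 20 adjusted over the list alone (camera adjusted p = 2.92e-07, and adjusted p = 0.103 with an estimated correlation). PIK3IP1, an inhibitor of PI3 kinase, fell from 683 ± 94.5 to 10.1 ± 1.59 CPM, 67.8-fold (edgeR adjusted p = 1.59e-05). KLF3 and ZFP36L2 fell 42.7-fold and 31.6-fold, and KLF2, which drives S1PR1 expression, fell from 45.1 ± 25.1 to 2.54 ± 1.65 CPM, 19.1-fold. Of immediate early genes, 0 rose and 18 fell of 25 tested, or 0 and 18 adjusted over the list alone (camera adjusted p = 6.37e-07, and adjusted p = 0.332 with an estimated correlation). JUN, FOSL2 and ZFP36 fell 58.1-fold, 16-fold and 30.4-fold. FOS varied among the fresh libraries, from 231 to 1164 CPM. The fitted log2 fold change of FOS (-8.11) moved by over 1.5 times in fold when 1 library was left out, to -7.19 without fresh replicate 3.

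Of cytosolic ribosomal protein genes, 0 rose and 26 fell of 30 tested, or 0 and 26 adjusted over the list alone (camera adjusted p = 3.46e-08, and adjusted p = 0.123 with an estimated correlation). RPL5 and RPL30 fell from 956 ± 118 to 228 ± 11.1 CPM and from 186 ± 19.1 to 39 ± 2.88 CPM, 4.19-fold and 4.76-fold. These genes have many processed pseudogenes that can take their reads. The members that did not pass were RPLP1, RPLP2, RPL8 and RPL18, whose mean levels were 562 ± 261 CPM in fresh and 493 ± 55.1 in cultured cells, 362 ± 224 CPM in fresh and 214 ± 13.8 in cultured cells, 519 ± 165 CPM in fresh and 399 ± 35.7 in cultured cells and 436 ± 365 CPM in fresh and 296 ± 28.3 in cultured cells, in that order. Fresh replicate 2 held the lowest fresh level of each, and without it RPLP1, RPLP2 and RPL18 passed as lower (adjusted p = 0.0445, 0.00109 and 0.00261). RPL8 passed with upper-quartile factors (adjusted p = 0.0477, and 0.0477 to 0.69 over all alternatives). The direction of RPLP1 and RPL18 also depended on the setting, with log2 fold changes of 0.051 for RPLP1 without fresh replicate 3 and of 0.37 with limma-voom and 0.19 with the replicate block for RPL18.

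Of interferon-stimulated genes, 24 rose and 0 fell of 28 tested, or 24 and 0 adjusted over the list alone (camera adjusted p = 6.16e-06, and adjusted p = 0.426 with an estimated correlation). OAS3 and OAS2, sensors of double-stranded RNA, rose from 14.7 ± 6.13 to 452 ± 209.8 CPM and from 16.4 ± 7.15 to 451 ± 199.9 CPM, 30.9-fold and 27.5-fold, and IFI35 rose 16.5-fold (edgeR adjusted p = 0.000138). Cultured replicate 3 held the lowest cultured levels of OAS3, OAS2 and IFI27, with OAS3 at 232 CPM against 649 and 476, and IFI27 at 3.6 against 158 and 290.4. IFI27 rose in the edgeR test (adjusted p = 0.0064) and not with limma-voom (adjusted p = 0.0726, and 2.15e-06 to 0.0726 over all alternatives). IFIT2, IRF9, HERC5 and EIF2AK2 did not pass, with log2 fold changes of 1.29 ± 0.96, 0.02 ± 0.31, 0.78 ± 0.43 and 0.22 ± 0.30. HERC5 passed without cultured replicate 3 (adjusted p = 0.0216, and 0.0216 to 0.69 over all alternatives), IFIT2 was at -0.82 without cultured replicate 1, EIF2AK2 was at -0.10 without it and at -0.042 with upper-quartile factors, and IRF9 was at -0.24 with those factors, at -0.13 with the 5 CPM filter, and at -0.25 and -0.068 without fresh replicate 2 and cultured replicate 2. With 1 library left out, the fitted log2 fold change of IFI27 (6.84) moved by over 1.5 times in fold, to 8.11 without fresh replicate 1; 6.23 without fresh replicate 3; 6 without cultured replicate 2; 7.46 without cultured replicate 3.

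**Figure D2:**
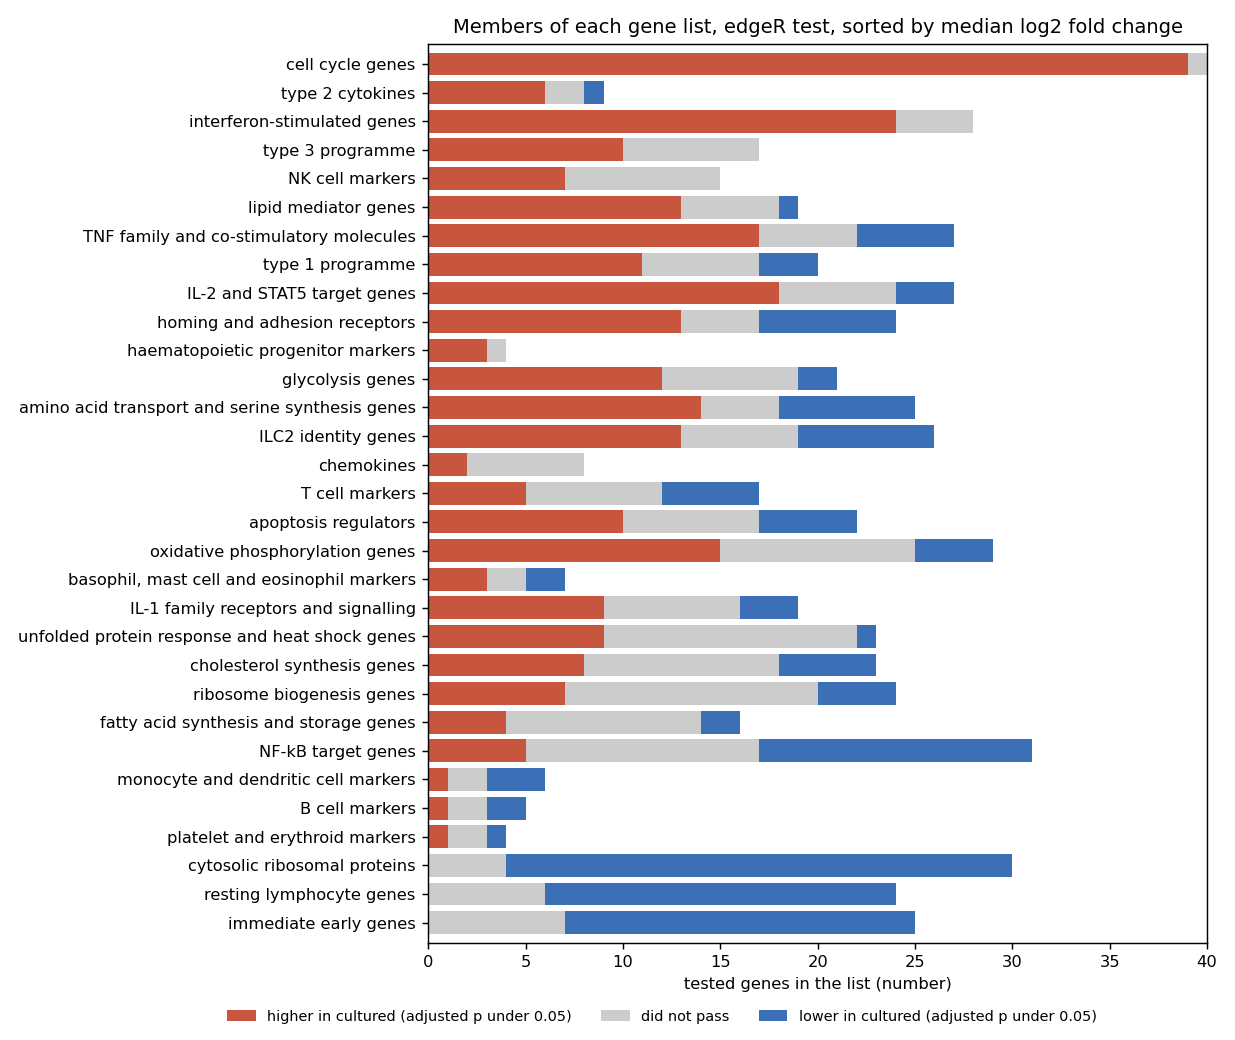
Number of tested members of each gene list (horizontal axis) that were higher in cultured cells (red), lower (blue) or did not pass (grey) in the edgeR test at an adjusted p of 0.05, for the 31 lists with at least 4 tested members. Cell cycle genes sit near the top with 39 higher and none lower, and resting lymphocyte genes near the bottom with 18 lower and none higher.

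Markers of other blood cells were measured because sorted ILC2s can hold traces of them. Of T cell markers, 5 rose and 5 fell of 17 tested, or 5 and 5 adjusted over the list alone (camera adjusted p = 0.481). TRBC2 and TRDC, constant region genes of T cell receptors, rose from 159.8 ± 18.3 to 599 ± 79.6 CPM and from 112 ± 25 to 422 ± 44.7 CPM, and LCK, UBASH3A and TRGC1 also rose. TRAT1, CD28, CD8A, CD6 and LAT fell. CD8A and LAT did not pass with the replicate block (adjusted p = 0.0836 and 0.0641), and LAT did not with limma-voom (0.0559). Over all alternatives the adjusted p of CD8A was 0.019 to 0.136 and that of LAT 0.00484 to 0.12. Calls were also lost for CD8A without fresh replicate 2 or cultured replicates 1 or 2 (adjusted p from 0.0877 to 0.136), for CD6 without fresh replicate 1 or cultured replicates 1, 2 or 3 (adjusted p from 0.0553 to 0.104) and for LAT without fresh replicates 1 or 2 or cultured replicates 1, 2 or 3 (adjusted p from 0.0557 to 0.12). Of NK cell markers, 7 rose and 0 fell of 15 tested, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.0354, and adjusted p = 0.451 with an estimated correlation), and the list did not pass without cultured replicate 3 (adjusted p = 0.115). GZMB, the granzyme B gene, rose from 49 ± 55 to 2498 ± 1548 CPM, 51-fold. GNLY, the granulysin gene, did not pass (edgeR adjusted p = 0.094), with 397 CPM in cultured replicate 3 against 8.2 and 68.4. It passed without cultured replicate 1 (adjusted p = 0.0228) and without a count filter (0.00552, and 0.00552 to 0.644 over all alternatives). Of B cell markers, 1 rose and 2 fell of 5 tested, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.688). CD79B rose from 4.64 ± 4.48 to 89.9 ± 4.88 CPM, while CD79A and MS4A1 fell from 6.52 ± 4.33 to 0.406 ± 0.352 CPM and from 8.96 ± 6.15 to 0.433 ± 0.665 CPM. The fitted log2 fold changes of GZMB (5.67), CD79B (4.28) and MS4A1 (-4.85) moved by over 1.5 times in fold when 1 library was left out, to 7.14 for GZMB without fresh replicate 2; 5.28 for CD79B and -4.19 for MS4A1 without fresh replicate 3; -4.11 for MS4A1 without cultured replicate 1; -4.10 for MS4A1 without cultured replicate 2; -6.92 for MS4A1 without cultured replicate 3.

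Of monocyte and dendritic cell markers, 1 rose and 3 fell of 6 tested, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.413). FCN1 had 70 fresh and 0 cultured counts, at least 16.7-fold lower against a floor of 3 counts over the group. LYZ and CSF1R also fell and VCAN rose, at mean levels under 20 CPM in both groups. Without fresh replicate 2, the log2 fold change of LYZ moved from -3.75 to -2.80 and that of VCAN from 2.06 to 2.98. CSF1R did not pass without cultured replicates 2 or 3 (adjusted p from 0.0572 to 0.066), nor VCAN with upper-quartile factors (adjusted p = 0.0647, and 0.00667 to 0.123 over all alternatives) or without fresh replicates 1 or 3 or cultured replicates 1 or 2 (adjusted p from 0.06 to 0.123). Of basophil, mast cell and eosinophil markers, 3 rose and 2 fell of 7 tested, or 3 and 2 adjusted over the list alone (camera adjusted p = 0.597). GATA2, IL3RA and CCR3 rose, GATA2 from 0.72 ± 0.262 to 18.4 ± 10.1 CPM, and AKAP12 and PRG2 fell. PRG2, an eosinophil granule gene, had 67 fresh counts and 1 cultured count, a ratio of 47.8, with a 95% counting interval of 8.3 to 1917 for fresh over cultured. Lists with under 5 tested genes were read gene by gene. Of platelet and erythroid markers, 1 rose and 1 fell of 4 tested, or 1 and 2 adjusted over the list alone, with the haemoglobin gene HBB falling from 26 ± 19 to 0.252 ± 0.131 CPM. ITGB3, an integrin gene, had 0 fresh and 544 cultured counts, at least 254-fold higher against the same floor. Of progenitor markers, 3 rose and 0 fell of 4 tested, or 3 and 0 adjusted over the list alone, namely KIT, SPINK2 and HLF, and HLF did not pass without cultured replicate 1 (adjusted p = 0.0523). SPINK2 had 5 fresh counts and stood at 1.44 CPM in cultured replicate 1. Its log2 fold change of 6.28 was 5.54 without fresh replicate 1 and 9.98 without fresh replicate 3. All 13 mitochondrially encoded genes were listed at 0 in every library and could not be tested. With 1 library left out, the fitted log2 fold changes of PRG2 (-5.25) and HBB (-6.87) moved by over 1.5 times in fold, to -6.15 for HBB without fresh replicate 3; -7.12 for PRG2 without cultured replicate 2.

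Reads outside genes differed between the groups. Reads in no annotated feature made up 51.7% ± 0.385 of counted reads in fresh and 32.1% ± 2.45 in cultured libraries (n = 3 per group, 2-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow, and 0.4 after adjustment over the 8 measures compared). Reads ambiguous between genes made up 4.42% ± 0.0471 and 7.15% ± 0.308 (n = 3 per group, exact permutation p = 0.1, adjusted 0.4). The 100 most counted genes took 16.7% ± 0.837 of gene counts in fresh and 17.3% ± 1.61 in cultured libraries (exact permutation p = 0.7). The number of genes with at least 10 counts was 17337 ± 825 in fresh and 15325 ± 2392 in cultured libraries (exact permutation p = 0.3).

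**Figure D3:**
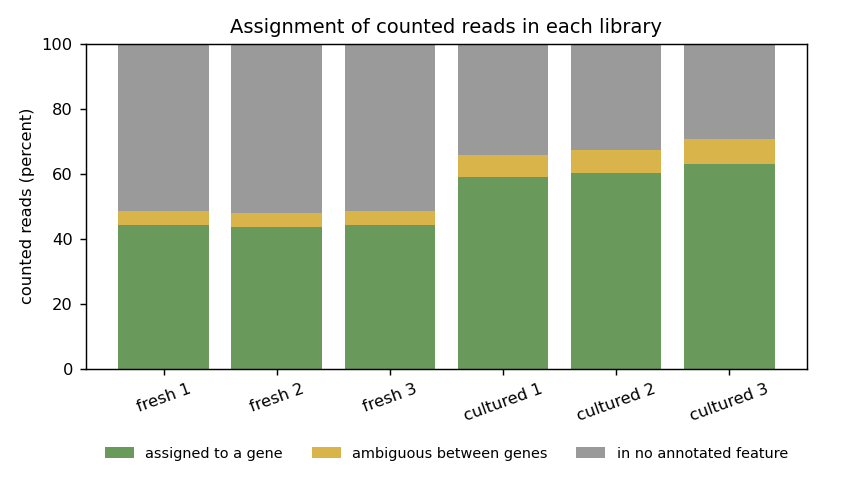
Percent of counted reads (vertical axis) in each of the 6 libraries that were assigned to a gene (green), ambiguous between genes (yellow) or in no annotated feature (grey). The fresh libraries had 51.4 to 52.1% of reads in no feature and the cultured libraries 29.4 to 34.2%.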

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

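The tests of genomic DNA, unspliced transcript, heat shock and other cell types in these paragraphs were chosen after the results were seen, and the test of gene length and GC content and the counts over other splits were planned.

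Reads ambiguous between genes, which no comparison of genes uses, made up 7.15% of counted reads in the cultured libraries, above the 4.42% of the fresh ones. Together with the lower share of reads in no feature (32.1% against 51.7%), this means that more cultured reads fell on annotated exons. Genomic DNA spread evenly through the fresh libraries would put reads on olfactory receptor genes, which lymphocytes do not transcribe, and the counts there reached at most 10.5% of the number such DNA would give. That argues against evenly sampled DNA as the source of the excess, although poly(A) priming need not sample DNA evenly. More unspliced transcript in fresh cells stays a candidate explanation: genes annotated inside introns of other genes differed from protein-coding genes by -1.48 in median log2 fold change (95% bootstrap interval -1.65 to -1.18). That interval covers the spread over genes and not over libraries. Medians were also below 0 for snRNA (-1.65), snoRNA (-1.71) and antisense genes (-0.73), so the fall was not particular to this class. Cell state and RNA handling are confounded with the groups and were not tested.

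Of 25 tested immediate early genes, 18 were higher in the fresh libraries (camera adjusted p = 6.37e-07, and adjusted p = 0.332 with an estimated correlation). Of 8 heat shock genes, 0 were higher in fresh cells (edgeR, and 0 at an unadjusted p under 0.05 and in every alternative, DESeq2 and limma-voom included). In cultured cells 3 were higher (1 to 4 over the alternatives, with 2 without fresh replicate 2 and 1 without fresh replicate 3 or any cultured replicate). Reads that fit both HSPA1A and HSPA1B, near-identical copies among the 8, may be missing from their counts. For the genes as counted, these values argue against a heat shock response in fresh cells beyond the level of the cultured cells. The cultured cells were the only baseline and may carry more of these transcripts themselves, so a lesser response in fresh cells cannot be judged. Monocytes are argued against as well, since LYZ, S100A8, S100A9, FCN1 and CD14 reached at most 6.68 CPM in a fresh library where FOS stood at 231 or more. Other members of the monocyte list stood higher, CSF1R at 15 CPM in fresh replicate 3 and VCAN at 7.25 in fresh replicate 2. Random lists matched on expression, length and GC content, in the fit with the replicate block, gave a median as low in 0 of 10000 draws (-2.43 in the list, -0.434 to 1.27 in 95% of draws). Handling of the cells, with such a lesser heat shock response or none, stays open. So does a difference between blood ILC2s and cells after stimulation in culture, whose duration the labels do not give. Both are confounded with the groups.

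Genes usually named for myeloid or cytotoxic cells, among them CCR1, CD33, CSF2RB, CCR3 and GZMA, were higher in the cultured libraries. Basophils, mast cells or eosinophils are argued against, since 9 of their granule and receptor genes reached at most 0.513 CPM in any cultured library, where the lowest of CCR1, CSF2RB, CD33 and CCR3 stood at 21.6, although GATA2 and IL3RA also rose. Monocytes are argued against by the 5 abundant genes LYZ, S100A8, S100A9, FCN1 and CD14, at most 2.46 CPM, although VCAN reached 19.3 CPM. NK cells stay open, since 5 of 20 NK cell markers, among them GZMB, PRF1, NKG7 and GNLY, reached at least 20% of the lowest GZMA level (534 CPM) in a cultured library, with GNLY at 397 and FCGR3A at 26.2 CPM in cultured replicate 3, while KLRD1 and KLRF1 stayed at or under 10.2 CPM. T cells stay open as well, since 6 of 21 T cell markers reached that level, among them TRBC2, TRDC, LCK, UBASH3A and TRGC1. CD3E reached 60.9 CPM in cultured replicate 3, against 15.6 and 16 in cultured replicates 1 and 2. CD3D reached 17.4 and CD3G 2 CPM, and CD4, CD5, CD6 and CD8A at most 1.23. Expression by the ILC2s themselves was not tested.

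Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split called 8778 genes and the highest other split 0 (edgeR; 53 to 234 genes at an unadjusted p under 0.05 in the other splits, and 9889 in the real one), and 1 of the 10 splits gave as many. For lists, the real split called 15 and the highest other split 14, and 1 of the 10 gave as many. At the preset correlation, camera called 6 to 14 lists in the other splits, which had no called genes. Every other split mixed fresh and cultured libraries on both sides, in unequal shares. Part of the group difference therefore stayed in the contrast, and the rest raised the variance within each side. Neither the gene counts nor the list counts of those splits show what unchanged data would give. Among the splits that part as many pairs as the real one, the others called 6, 13 and 7 lists.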

How the results depend on the processing

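Called genes kept their sign in every setting run. The number of genes past the threshold stayed within 1.5 times of 4419 higher and 4359 lower, except that an adjusted p under 0.01 left 2835 lower (3049 higher), by construction. With the replicate block there were 4478 higher and 4046 lower genes, with DESeq2 5101 and 4710, and with limma-voom 4957 and 4268. Upper-quartile factors moved the median log2 fold change of all tested genes by -0.262 (3759 higher, 5324 lower), and the 5 CPM filter by -0.159 (3386 and 3599), so log2 fold changes under about these sizes have no firm sign. Leaving out 1 library gave 3460 to 4665 higher and 3260 to 4723 lower genes, with fewer samples. Of 15 called lists (12 higher, 3 lower), 0 higher and 0 lower passed with an estimated correlation (smallest adjusted p 0.103), and 0 and 0 with the block and an estimated correlation, added after seeing the data. Estimated correlations were -0.0874 to 0.63. Lists near 0, such as resting lymphocyte genes (-0.0301, below the preset 0.01), also lost their calls. Correlated members cannot account for the loss in such lists, and the estimated setting also uses fewer degrees of freedom. A call lost in that setting thus does not by itself show that members vary together. With fry, which tests against no change and not against other genes, 5 lists were lower and 23 passed in all. Leaving out a library gave 10 to 13 higher lists and 3 lower each time. The replicate block ended the calls of amino acid (0.0523) and oxidative phosphorylation (0.0546) lists and of IRAK2, CD8A, LAT, GNL3 and HSPD1 (a heat shock gene, adjusted p 0.0529), brought CD3E past the threshold (0.0496) and changed no other call of a list or named gene. The reversed values were those of genes that did not pass. They were IL9 (-0.035 with upper-quartile factors), MCM7 (-0.043), EIF2AK2 (-0.042) and IRF9 (-0.24, and -0.13 with the 5 CPM filter), RPL18 (0.37 with limma-voom, 0.19 with the block), CD14 (0.56 with limma-voom, 0.0067 without a count filter), KLRF1 (-1.54 with limma-voom, -0.74 with the block) and FCGR3A (-1.89 and -0.44). Leaving out 1 library gave log2 fold changes on both sides of 0 for IL9 (-0.42 to 3.66), GATA3 (-0.22 to 0.077), IL1R1 (-0.28 to 1.07), EIF2AK2 (-0.10 to 0.51), IFIT2 (-0.82 to 1.85), RPLP1 (-0.56 to 0.051), IRF9 (-0.25 to 0.18), CD14 (-1.29 to 0.68), KLRF1 (-2.20 to 0.96) and FCGR3A (-2.21 to 1.78). The cause was not tested. The difference in no-feature share ranged from -20.6 to -18.2 points when a library was left out, that in ambiguous share from 2.57 to 2.88, in the share of the top 100 genes from -0.328 to 1.21, and in genes with 10 counts from -3214 to -822. Cultured replicate 3, with 5008778 counts, limits what can be said of genes with few counts.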

Other observations

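CSF2RB and IL2, which were in no list, changed and were chosen after their values were seen. CSF2RB, the signalling chain shared by receptors for IL-3, IL-5 and GM-CSF, rose from 1.08 ± 0.955 to 268 ± 111 CPM, 242-fold (edgeR adjusted p = 0.000152), while the cultured cells also carried more CSF2 and IL5. IL2 fell from 44.3 ± 10.6 to 0.402 ± 0.3 CPM, 96.7-fold (edgeR adjusted p = 9.64e-05), in cells cultured in added IL-2. IL3, a type 2 list member and neighbour of CSF2 on chromosome 5, fell while CSF2 rose. CCR3, the eotaxin receptor gene, had 0 counts in fresh replicates 1 and 2, while fresh replicate 3 held its 31 fresh counts (2.27 CPM). It stood at 26.6, 89.8 and 35.8 CPM in the cultured libraries. The fitted log2 fold changes of CSF2RB (7.92), IL2 (-6.60) and CCR3 (6.15) moved by over 1.5 times in fold when 1 library was left out, to 5.42 for CCR3 without fresh replicate 1; 8.50 for CSF2RB and 5.55 for CCR3 without fresh replicate 2; 12.43 for CCR3 without fresh replicate 3; -7.62 for IL2 and 5.44 for CCR3 without cultured replicate 2.

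Non-coding classes had lower median log2 fold changes than protein-coding genes, by differing amounts. Of 229 tested sense-intronic genes 94 were lower and 18 higher in cultured cells, with a median log2 fold change of -1.24, and of 75 snoRNA genes 39 were lower and 3 higher (median -1.71). Of 104 snRNA genes 48 were lower and 3 higher. Protein-coding genes had a median of 0.25. Antisense genes (-0.73), processed pseudogenes (-0.40) and lincRNA genes (-0.37) lay nearer to it. Differences between classes were not tested, except for sense-intronic genes. MALAT1, a nuclear long non-coding RNA, was the most counted gene in each fresh library (1.52 to 1.93% of gene counts) and fell 2.14-fold. Small RNAs without poly(A) tails are poorly captured by this kit, and without strand their counts can hold reads of host genes.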
